A study of Solanum lycopersicum with 9 samples.

How the data were processed

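RNA sequencing of leaves from tomato (Solanum lycopersicum cv Rutgers) was analysed in 3 groups of 3 independent biological replicates, collected 17 days post inoculation. Plants were inoculated mechanically with plasmids carrying a full-length copy of a mild (PSTVd-M) or a severe (PSTVd-S23) strain of potato spindle tuber viroid, or with the empty plasmid pUC9, which served as control. Per the labels, ribosomal RNA was depleted from total RNA, ERCC spike-in RNA was added, and libraries were read on an Ion Proton instrument. The study's design text speaks of more RNA samples than the 9 leaf libraries analysed here.

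The expected_counts values of 35768 tomato genes are estimated counts of reads per gene, computed by the authors before deposition with Partek software and not scaled between libraries. Between 4.90 and 5.70% of the non-zero values per library were not whole numbers, and all values were rounded before testing. The aligner, the counting settings, the use of strand and the versions are not given in the sources used here, so reads shared between near-identical copies or between overlapping genes on opposite strands could not be assigned again. The p-value and the step-up FDR (p_value) of each gene in a further table were computed by the authors before deposition for mild strain against control, severe strain against control and both strains against control. The same table from the authors gives each ratio on a linear scale, after a normalization that is not given in the sources used here. It also supplied gene descriptions, symbols and coordinates on the SL3.0 build for 22142 genes, of which 1663 had a symbol. The 5034 genes with a count that it lacks had at most 8 counts in any library. The count table holds 0 ERCC rows, so no scaling to spike-ins was made. A table of RefSeq names was not used here because it holds none of the gene identifiers of the counts.

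Library totals were between 1560631 and 5162865 counts. A fold against a group without any count was computed against a floor of 3 counts over the whole group and is given as a lower bound. With 1 to 3 counts in the lower group the ratio is given with its exact 95% counting interval. Such bounds and intervals cover counting error only. Reads carried no molecular identifiers.

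Genes were kept by the edgeR function filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15101 of the 26716 genes with a count in any library. Libraries were scaled by TMM. A negative binomial model with 1 mean per group was fitted to all 9 libraries with 6 residual degrees of freedom, and each pair of groups was compared with the edgeR quasi-likelihood F test, two-sided. The biological coefficient of variation was 0.230. P values were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are in CPM (counts scaled to a library total of 1e6) of the TMM-scaled library, as mean ± SD over the 3 libraries of a group. Log2 CPM for principal components and library scores used a pseudocount of 2.

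Gene groups were 39 lists of descriptions and symbols, covering pathways and cell type markers, whose terms were fixed before the data were examined, as were the groups, the comparisons, the tests, the rule for named genes and most of the other settings tried. After descriptions were seen, 17 genes were taken out of the lists for pathogenesis-related proteins, jasmonate and phloem because a fragment of a word had matched. Lists with at least 5 tested members were compared with all other genes by camera from limma with a preset correlation of 0.01 between genes, two-sided, and adjusted over the 39 lists. The same test was also run with the correlation estimated from the data. Counts of called members are given after adjustment over all genes and after adjustment over the list alone. The lists of photosynthetic and plastid ribosomal genes hold copies of organelle genes annotated in the nuclear assembly. By description, 615 genes were such copies or rRNA genes, and both kinds were left out together where organelle copies are left out.

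By the rule for named genes, each comparison named up to 8 genes per direction with the largest log2 fold change among called genes whose groups did not overlap and whose mean count reached 20 in the higher group, and up to 4 members per list with the smallest p. The rule named 327 genes, and the text gives those that show a list best, chosen among them after their values were seen. Other settings were followed for genes named by fold change in any comparison or as list members in PSTVd-S23 against control. Where a call of such a gene was lost under another setting, another named gene was preferred or the loss is stated. Some named genes lie at chromosome 0, the label of sequence not assigned to a chromosome.

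Alternatives were DESeq2, limma-voom, DESeq2 size factors inside edgeR, no normalization beyond library totals, no low-count filter, a stricter filter of at least 2 CPM in at least 3 libraries, organelle copies left out, a fit to the 6 libraries compared, the replicate number as a block, leaving out each library in turn, and an estimated correlation in the list test. Added after the data were seen were organelle copies left out of the lists, the fry test of limma, which compares a list with no change and not with other genes, and PSTVd-M medians without PSTVd-M replicate 3. Replicate numbers were tested as pairs. Across the 9 pairs of libraries with the same number in different groups, correlations of log2 CPM after removal of group means ran from -0.261 to 0.151. Of the 9 libraries 2 were closest to one of their own number. The fit reported used no replicate block, since the labels do not say that a number marks a shared plant, tray or day.

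The overlap between strains shares its control libraries. For shared genes, covariance and correlation, 20 simulated data sets left both strains equal to control. For the PSTVd-M medians and percentages of genes called with PSTVd-S23, 20 others kept PSTVd-M at control and PSTVd-S23 at its own mean. The procedure was tested on simulated data with 200 changed genes. edgeR found 30% of genes changed by 1 and 84% of those changed by 2 on the log2 scale, and 8 of its 122 calls were false. A list of 60 genes shifted by 0.5 was called and 0 of 38 unshifted lists were. Spreads of medians came from 1000 bootstrap draws. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.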

Results

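Gene expression was measured by sequencing of rRNA-depleted RNA from tomato leaves at 17 days post inoculation, an early stage of symptoms. Leaves came from plants inoculated with the mild strain PSTVd-M, the severe strain PSTVd-S23 or the empty plasmid pUC9, with 3 libraries in each group. Potato spindle tuber viroid is a small circular RNA that codes for no protein. The control libraries held 1833745, 2509699 and 5162865 counts for replicates 1 to 3. The PSTVd-M libraries held 2556589, 2851942 and 2046415 counts, and the PSTVd-S23 libraries 4017220, 1560631 and 2752186. Of 26716 genes with a count, 15101 were tested.

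Genes described as organelle copies or rRNA took 33.8, 36 and 32.3% of counts in control. They took 35.3, 38.3 and 33.8% in PSTVd-M and 29.2, 27 and 29.2% in PSTVd-S23. Organelle copies and rRNA were not counted apart. The first principal component held 44.2% of the variance. A score over the genes called with PSTVd-S23 placed the control libraries at 1.5, 1.52 and -3.02% of the PSTVd-S23 mean and the PSTVd-M libraries at 18.6, 25.0 and 39.9%. PSTVd-M replicate 3 was therefore the library of its group nearest to PSTVd-S23.

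**Figure D1:**
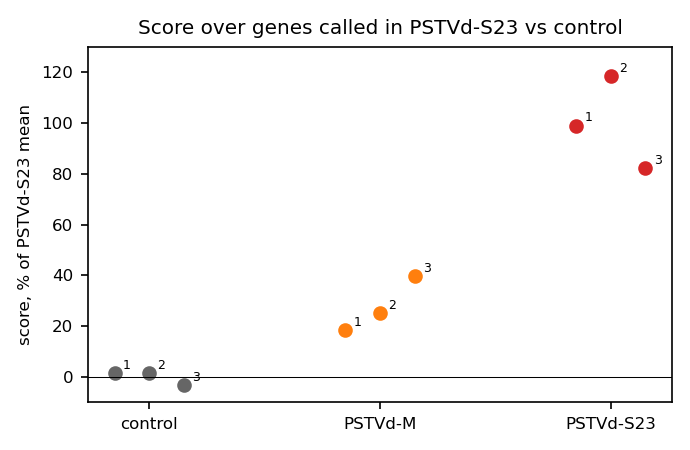
Score of each library over the genes called in PSTVd-S23 against control, as a percentage of the PSTVd-S23 mean, by group; each dot is 1 library with its replicate number. The PSTVd-M libraries stood at 18.6, 25.0 and 39.9%, and the PSTVd-S23 libraries, whose calls define the score, at 99.0, 118.7 and 82.3%.

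The comparison of PSTVd-M with control asks how leaves respond to a strain that causes mild symptoms. With edgeR 4 genes passed the test, all of them lower in PSTVd-M. Phosphoenolpyruvate carboxylase kinase (Solyc04g009900.3, SL3.0 chromosome 4, 3214862 to 3216340), which activates phosphoenolpyruvate carboxylase by phosphorylation, fell from 72.7 ± 1.83 CPM in control to 22.9 ± 5.06 CPM (SD, n = 3), a log2 fold change of -1.67 ± 0.20 (SE, adjusted p = 0.00676). Lipoxygenase C (loxc, Solyc01g006540.3, chromosome 1, 1113465 to 1123470), an enzyme of lipid oxidation, fell from 50.5 ± 10.4 to 16.0 ± 4.32 CPM (log2 -1.64 ± 0.25, adjusted p = 0.0346). Sn-1 (Solyc04g005700.3, chromosome 4, 455934 to 457663) fell from 75.1 ± 4.12 to 24.8 ± 4.05 CPM (log2 -1.60 ± 0.23, adjusted p = 0.0296). A sieve element occlusion gene (Solyc03g111820.3, chromosome 3, 63920851 to 63923835), whose family forms protein bodies in the phloem, fell from 208 ± 37.6 to 88.8 ± 9.03 CPM (log2 -1.22 ± 0.19, adjusted p = 0.0368).

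At an unadjusted p under 0.05 stood 1148 genes, against 755.05 by chance. That no gene was called higher holds for edgeR with the filter, all 9 libraries and no replicate block. With no filter edgeR called 147 higher and 92 lower, with only the 6 samples compared 2 and 5, with a replicate block 1 and 4, and without PSTVd-M replicate 1 3 and 3. DESeq2 called 25 higher and 23 lower, and limma-voom called the same 4 genes. The 3 libraries of each group did not overlap for 12.7% of all genes, against 10% by chance. Without PSTVd-M replicate 2 no gene was called, without control replicate 1 or PSTVd-S23 replicate 1 the count was 1, and without control replicate 2 it was 2. The kinase was lost without PSTVd-M replicate 2 (adjusted p = 0.0994, range over alternatives 7.87e-10 to 0.0994). The other 3 genes were lost without that library too, at 0.208 to 0.267, and each without control replicates 1 and 2, at 0.0782 to 0.144, and without PSTVd-S23 replicate 1, at 0.0540 to 0.0603. Sn-1 was further lost without control replicate 3 (0.0714) or PSTVd-M replicate 1 (0.102), loxc without PSTVd-M replicate 3 (0.133), and the sieve element gene without PSTVd-M replicate 1 (0.0840) or 3 (0.154) and with a replicate block (0.0973).

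Among the 39 gene lists, 4 passed the list test in PSTVd-M against control although none of their members was called over all genes. Disease resistance genes of the NBS-LRR type, which encode intracellular immune receptors, had a median log2 fold change of 0.17 over 99 members (adjusted p = 0.0371, and adjusted p = 0.453 with an estimated correlation, range over alternatives 0.0134 to 0.453). The 230 receptor-like kinases had a median of 0.14 (adjusted p = 0.0371, and adjusted p = 0.453 with an estimated correlation, range 0.0134 to 0.453). Over this list alone 1 member was higher. Toward lower values, 82 genes of epidermis and cuticle had a median of -0.21 (adjusted p = 0.0169, and adjusted p = 0.548 with an estimated correlation, range 0.00786 to 0.548). The 199 genes of dividing cells had a median of -0.16 (adjusted p = 0.000250, and adjusted p = 0.453 with an estimated correlation, range 7.22e-06 to 0.453). With an estimated correlation none of the 39 lists was called, and none by fry, which asks whether a list changed at all rather than whether it differs from other genes.

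These list calls were lost without single libraries, although all 3 PSTVd-M libraries lay beyond all 3 controls in the mean log2 CPM of 3 of the 4 lists, all but dividing cells. For resistance genes the means relative to control were 0.20, 0.13 and 0.34 in PSTVd-M and 0.01, 0.06 and -0.06 in control. Without control replicate 3 all of them were lost, with adjusted p of 0.319 for resistance genes, 0.140 for receptor-like kinases, 0.187 for epidermis and 0.319 for dividing cells. Resistance genes were also lost without control replicate 1 (0.0714), PSTVd-M replicate 3 (0.238) or PSTVd-S23 replicate 2 (0.0541). Receptor-like kinases were lost without control replicate 1 (0.0714) or 2 (0.0855) or PSTVd-M replicate 3 (0.369), epidermis without PSTVd-M replicate 3 (0.0645) and dividing cells without PSTVd-M replicate 2 (0.0784). With no low-count filter the first 3 lists were lost, at 0.0722 to 0.0979.

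The remaining 35 lists were not called in PSTVd-M, with adjusted p of 0.0877 to 0.949 and medians of -0.36 to 0.30. RNA silencing genes had 3 members higher after adjustment over the list alone and none over all genes. Dicer-like 2b, which cuts double-stranded RNA into small RNAs, stood at 41.1 ± 1.96 CPM in PSTVd-M and 23.6 ± 4.79 in control (adjusted p = 0.283). WRKY transcription factors, regulators of defence genes, had a median of 0.30 and 1 member higher over the list alone (adjusted p of the list test 0.150). Glandular trichome genes had 3 members lower over the list alone, and the light-harvesting and photosystem list had a median of -0.00 (adjusted p = 0.876). Its mean log2 CPM relative to control was 0.11, 0.18 and -0.22 in PSTVd-M replicates 1 to 3, so the libraries split. Calvin cycle genes (0.26, 0.29 and -0.26) and chlorophyll and carotenoid genes (0.09, 0.15 and -0.15) split likewise. Without PSTVd-M replicate 3, 3 lists were called, 2 toward higher and 1 toward lower values, and 1 was among the 4 above. Members named by the rule without a call included the ethylene receptor gene etr5 (Solyc11g006180.2), at 16.6 ± 2.18 CPM in control and 37.4 ± 1.41 in PSTVd-M (adjusted p = 0.0986). A further one was the salicylate-related NIMIN2b gene Solyc03g119600.1, at 2.03 ± 0.391 and 10.5 ± 3.44 CPM (adjusted p = 0.109). Median, mean and test differed in sign only in lists with adjusted p of 0.756 to 0.949.

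In PSTVd-S23 against control, the comparison that asks what the severe strain does, single genes of defence, RNA silencing and protein folding rose and single genes of photosynthesis fell, while no gene list was called with an estimated correlation. The pathogenesis-related gene PR1 (Solyc00g174340.2, chromosome 0, 17166163 to 17168118), a marker of salicylate-dependent defence, rose from 11.1 ± 4.51 to 401 ± 226 CPM (SD, n = 3), a log2 fold change of 5.10 ± 0.50 (SE, adjusted p = 1.79e-05). The gene of protein disulfide-isomerase (Solyc06g005940.3, chromosome 6, 921054 to 925706), which folds secreted proteins, rose from 76.8 ± 6.57 to 319.5 ± 59.5 CPM (log2 2.06 ± 0.18, adjusted p = 9.48e-06). Dicer-like 2b (Solyc11g008540.2, chromosome 11, 2713505 to 2724608) rose from 23.6 ± 4.79 to 120.0 ± 26.3 CPM (log2 2.37 ± 0.21, adjusted p = 1.15e-05). The chlorophyll a/b-binding gene cab5a (Solyc12g006140.2, chromosome 12, 693028 to 694540), part of the light-harvesting antenna, fell from 505 ± 128 to 41.7 ± 27.3 CPM, 11.9-fold lower (log2 -3.57 ± 0.36, adjusted p = 2.09e-05). A lipid-transfer type gene (Solyc03g121900.1, chromosome 3, 71407863 to 71408184) fell from 75.6 ± 6.59 to 2.96 ± 3.22 CPM, 24.3-fold lower (log2 -4.60 ± 0.45, adjusted p = 1.97e-05).

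Of 15101 genes tested with edgeR, 2116 passed, 1186 higher and 930 lower, and 866 and 569 of them changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 stood 4194 genes. The groups did not overlap for 31.1% of all genes, against 10% by chance, and for 2063 of the 2116 called. The number called dropped to 1352 without PSTVd-S23 replicate 1 and to 1309 without PSTVd-S23 replicate 2. With no normalization the median of all genes shifted by 0.28 toward PSTVd-S23 and the split became 2314 higher and 454 lower. All directions are relative to the TMM scaling.

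**Figure D2:**
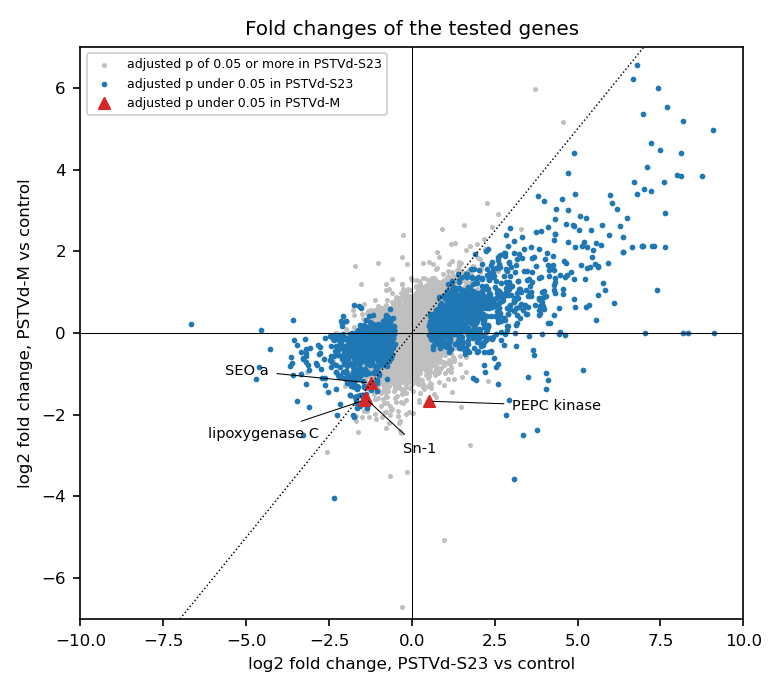
Log2 fold changes of the 15101 tested genes in PSTVd-S23 against control (horizontal axis) and in PSTVd-M against control (vertical axis); blue dots are the 2116 genes called in PSTVd-S23, red triangles the 4 called in PSTVd-M, and the dotted line marks equal values. The triangle of phosphoenolpyruvate carboxylase kinase stands at -1.67 in PSTVd-M and 0.51 in PSTVd-S23; fitted values of genes with no counts in a group depend on the prior count.

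Pathogenesis-related genes, which encode chitinases, glucanases and other antimicrobial proteins, had 25 of 71 members higher and 7 lower (27 and 10 adjusted over the list alone). Chitinase Z15141 (Solyc02g082920.3) rose from 5.10 ± 0.996 to 91.2 ± 35.8 CPM and chitinase Z15140 (Solyc10g055810.2) from 78.4 ± 46.5 to 1139 ± 318 CPM. A second PR1 gene, Solyc00g174330.3, whose coordinates overlap those of the first, had no counts in control and was at least 37.6-fold higher. The median log2 fold change of the list was 0.24 (adjusted p = 0.0474, and adjusted p = 0.31 with an estimated correlation, range over alternatives 0.00749 to 0.31). That call was lost without any 1 of the control and PSTVd-M libraries (0.0827, 0.150 and 0.0652 without control replicates 1, 2 and 3, and 0.0563, 0.0767 and 0.0530 without PSTVd-M replicates 1, 2 and 3). It was also lost with no normalization (0.307), with either other filter (0.101 and 0.205) and with organelle copies left out of the lists (0.0524).

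WRKY genes had 11 of 30 members higher and none lower (13 and 0 adjusted over the list alone), with a median of 0.83 (adjusted p = 3.83e-05, and adjusted p = 0.256 with an estimated correlation, range 5.88e-07 to 0.256). WRKY81 (Solyc09g015770.3) rose from 15.3 ± 4.24 to 139.7 ± 6.24 CPM, and WRKY45 (Solyc08g067360.3), without counts in control, was at least 58.9-fold higher. Among 39 subtilisin-like proteases 5 were higher and 4 lower (6 and 4 over the list alone). Pathogen-induced p69b (Solyc08g079870.3) rose from 31.0 ± 10.5 to 619.9 ± 253 CPM, while Solyc10g084320.2 fell from 23.8 ± 6.14 to 5.65 ± 2.27 CPM. That list was not called (adjusted p = 0.774), with a median of -0.09, a mean of 0.24 and a test toward higher. Proteinase inhibitors, 2 of 17 higher and 1 lower (the same numbers over the list alone), were not called either (0.774), and their median of 0.21 and mean of 0.28 were positive while the test leaned lower.

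NBS-LRR resistance genes had 25 of 99 members higher and 2 lower (33 and 2 over the list alone), with a median of 0.49 (adjusted p = 0.000356, and adjusted p = 0.162 with an estimated correlation, range 0.000118 to 0.162). Solyc04g007070.3 went from 106 ± 2.29 to 266 ± 4.10 CPM. Receptor-like kinases had 67 of 230 members higher and 23 lower (74 and 31 over the list alone), with a median of 0.25 (adjusted p = 0.00273, and adjusted p = 0.2 with an estimated correlation, range 1.37e-05 to 0.2). The kinase Solyc09g083200.3 had a log2 fold change of 5.29 ± 0.59 (adjusted p = 3.79e-05). Calcium signalling genes had 19 of 113 members higher and 4 lower (20 and 4 over the list alone), with a median of 0.30 (adjusted p = 0.00609, and adjusted p = 0.256 with an estimated correlation, range 0.00173 to 0.256). The glutamate receptor-like gene GLR2.5 (Solyc06g063210.3), of a family of calcium-permeable channels, rose from 2.41 ± 1.5 to 43.7 ± 18.3 CPM.

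RNA silencing genes moved in both directions, with 6 of 30 higher and 2 lower (7 and 3 over the list alone), and the list was not called (adjusted p = 0.549). Dicer-like 2d (Solyc11g008530.2) rose from 5.05 ± 2.49 to 33 ± 9.94 CPM (log2 2.68 ± 0.36, adjusted p = 0.000157). The RNA-directed RNA polymerase gene rdrp (Solyc05g007510.3, chromosome 5, 2062291 to 2071246), whose product makes double-stranded RNA, rose from 44 ± 9.72 to 143 ± 23.8 CPM (log2 1.71 ± 0.23, adjusted p = 0.000201). Argonaute 10a (Solyc09g082830.3, chromosome 9, 68916353 to 68924565), a binding protein of small RNAs, fell from 55.3 ± 3.30 to 18.5 ± 3.59 CPM (log2 -1.61 ± 0.21, adjusted p = 0.000142). The median of -0.07 was opposite in sign to the mean of 0.14 and became 0.23 with no normalization. Callose synthases and plasmodesmata had 1 of 11 lower (1 over the list alone), a median of -0.12 that became 0.14 with no normalization, and no call (0.137).

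Hormone lists gave 1 call. Auxin genes had 4 of 76 members higher and 13 lower (6 and 16 over the list alone), with a median of -0.33 (adjusted p = 0.0169, and adjusted p = 0.254 with an estimated correlation, range 0.00770 to 0.254). An auxin-repressed gene (Solyc02g077880.3) fell from 1282 ± 297 to 434 ± 112 CPM and iaa7 (Solyc06g053830.3), of a family of auxin response repressors, from 10.7 ± 0.171 to 2.52 ± 1.00 CPM. The call was lost without control replicate 1 (0.0752), control replicate 2 (0.0525) or PSTVd-S23 replicate 3 (0.0808) and with no or a stricter low-count filter (0.178 and 0.0988). Ethylene genes had 12 of 61 higher and 3 lower (13 and 4 over the list alone, 0.195), with a median of 0.01. LeACO1 (Solyc07g049530.3, chromosome 7, 59957577 to 59960266), for an enzyme of the last step of ethylene synthesis, stood at 74.5, 257.6 and 79.4 CPM in the PSTVd-S23 libraries and at 2.79 ± 3.15 CPM in control (log2 5.82 ± 0.64, adjusted p = 3.47e-05). Salicylate genes had 5 of 14 higher and none lower (6 and 1 over the list alone, 0.278). The immune regulator EDS1 (Solyc06g071280.3) rose from 44.4 ± 5.67 to 133 ± 51.3 CPM, and the list's median was -0.01, its mean 1.06 and its median with no normalization 0.28.

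The other hormone lists were not called. Jasmonate genes had 3 of 21 higher and 2 lower (3 and 5 over the list alone, adjusted p = 0.391), among them the fall of loxc to 18.3 ± 2.83 CPM. Their median was -0.18, their mean 0.24 and their median with no normalization 0.10. Gibberellin genes had 1 of 15 higher and 4 lower (2 and 4 over the list alone, 0.460) with a median of -0.30. The fallen Snakin-2-like gene Solyc03g113910.3 of that list belongs to a family of antimicrobial peptides. Brassinosteroid and sterol genes had 3 of 38 lower (3 over the list alone, 0.0927), and their median of -0.27 became 0.00 with no normalization. Cytokinin genes had 2 of 35 higher and 5 lower (2 and 7 over the list alone, 0.234) with a median of -0.30. Among them were 2 APRR2-like genes, pseudo-response regulators that the clock list holds too. Abscisic acid genes had 4 of 67 higher and 7 lower (5 and 7 over the list alone, 0.740), a median of -0.07, a mean of 0.03 and a median of 0.22 with no normalization.

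Light-harvesting and photosystem genes had 2 of 232 members higher and 96 lower (4 and 127 over the list alone). The list median was -0.77 (adjusted p = 9.64e-27, and adjusted p = 0.195 with an estimated correlation, range 9.20e-34 to 0.195). Organelle copies apart, 53 of 76 nuclear members were lower and none higher with edgeR, with a median of -1.18 that was -0.90 with no normalization, where 47 were lower and 1 higher. A chlorophyll a/b-binding gene on chromosome 2 (Solyc02g071000.1, 41087550 to 41088348) fell 12.4-fold, from 2317 ± 585 to 186 ± 131 CPM. The summed level of 34 chlorophyll a/b-binding genes, some near-identical in sequence, was 69156 ± 14557 CPM in control, 60913 ± 6020 in PSTVd-M and 16615 ± 7098 in PSTVd-S23.

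Chlorophyll and carotenoid synthesis had 1 of 38 members higher and 9 lower (1 and 9 over the list alone), with a median of -0.25 that became 0.02 with no normalization (adjusted p = 0.000927, and adjusted p = 0.31 with an estimated correlation, range 2.75e-05 to 0.31). The H subunit of magnesium chelatase (Solyc04g015750.3, chromosome 4, 6034388 to 6040395), at the entry to chlorophyll synthesis, fell from 1918 ± 193 to 409 ± 203 CPM (log2 -2.23 ± 0.30, adjusted p = 0.000168). Protochlorophyllide oxidoreductase 3 (POR3, Solyc10g006900.3) fell from 794 ± 61.3 to 143 ± 106 CPM. Calvin cycle and photorespiration had 3 of 28 lower (2 over the list alone), with a median of -0.39 (adjusted p = 0.00273, and adjusted p = 0.394 with an estimated correlation, range 0.000421 to 0.394). It was lost with organelle copies left out (0.127), and fry did not call the list (0.111). Plastid ribosomal proteins had 2 of 126 higher and 2 lower (0 and 0 over the list alone), with a median of -0.21 that became 0.06 with no normalization (adjusted p = 0.0457, and adjusted p = 0.47 with an estimated correlation, range 0.00971 to 0.47). Their call was lost without control replicate 2 (0.0525) or 3 (0.332), PSTVd-M replicate 1 (0.0513) or 2 (0.0565), or PSTVd-S23 replicate 1 (0.0740) or 2 (0.141), without organelle copies (0.391), and at 0.0593 to 0.0955 under other filters and no normalization, and fry did not call the list (0.175).

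Cytosolic ribosomal protein genes had 31 of 174 members higher and 1 lower (41 and 1 over the list alone), with a median of 0.40 (adjusted p = 6.23e-11, and adjusted p = 0.104 with an estimated correlation, range 4.79e-13 to 0.104). The gene of ribosomal protein S21 (Solyc01g066840.3) went from 71.3 ± 3.53 to 146 ± 6.05 CPM. Translation factors had 9 of 116 higher and 1 lower (7 and 1 over the list alone), with a median of 0.21 (adjusted p = 0.0258, and adjusted p = 0.256 with an estimated correlation, range 0.00280 to 0.256). They were lost without control replicate 3 (0.0652) or PSTVd-S23 replicate 2 (0.0765). Elongation factor 1-alpha (Solyc11g069700.2, chromosome 11, 54602015 to 54604910) rose from 69 ± 13.3 to 389 ± 146 CPM. The 1 member that fell, Solyc09g074930.3, is described as a rubber elongation factor, a protein of rubber particles and not of translation.

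Endoplasmic reticulum folding genes had 11 of 30 members higher and 1 lower (13 and 1 over the list alone), with a median of 0.49 (adjusted p = 2.51e-05, and adjusted p = 0.0686 with an estimated correlation, range 7.21e-08 to 0.0686). The chaperone gene bipgrp78 (Solyc08g082820.3, chromosome 8, 65610083 to 65614371) rose from 110.2 ± 25.0 to 390.2 ± 104 CPM (log2 1.81 ± 0.22, adjusted p = 7.76e-05), and calnexin (Solyc03g118040.3) from 142 ± 18.6 to 475 ± 123 CPM. Heat shock proteins and chaperones had 13 of 183 higher and 8 lower (11 and 6 over the list alone) and were not called (0.740, median 0.04). Glutathione S-transferases and peroxidases, enzymes of detoxification and oxidative stress, had 32 of 148 higher and 7 lower (39 and 13 over the list alone), with a median of 0.10 (adjusted p = 0.0303, and adjusted p = 0.162 with an estimated correlation, range 0.00295, by fry, to 0.162). A peroxidase gene (Solyc04g071890.3) rose from 31.3 ± 12.7 to 228 ± 39.0 CPM. The list also holds iron superoxide dismutase (fesod, Solyc06g048410.3), a plastid antioxidant enzyme, which rose from 33.6 ± 4.63 to 88.9 ± 10.1 CPM. The call was lost without PSTVd-S23 replicate 1 (0.0740) and with no normalization (0.0511).

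Expansins and xyloglucan enzymes, which loosen walls during growth, had 3 of 36 higher and 9 lower (3 and 11 over the list alone), with a median of -0.38 (adjusted p = 0.0213, and adjusted p = 0.256 with an estimated correlation, range 0.00593 to 0.256). They were lost without PSTVd-S23 replicate 2 (0.0516) and with no low-count filter (0.0631). The expansin expa4 (Solyc09g010860.3) fell from 19.1 ± 2.43 to 7.56 ± 1.45 CPM. Pectin enzymes had 3 of 66 higher and 9 lower (3 and 11 over the list alone), with a median of -0.35 (adjusted p = 0.00805, and adjusted p = 0.39 with an estimated correlation, range 0.000421 to 0.39), and were not called by fry (0.0931). A pectinesterase gene (Solyc06g009190.3) fell from 119 ± 17.0 to 44.7 ± 13.7 CPM. One risen member, Solyc03g083730.1, encodes an inhibitor of such enzymes.

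Nitrogen assimilation and transport had 12 of 65 members higher and none lower with edgeR (12 and 0 over the list alone), with a median of 0.02 (adjusted p = 0.0336, and adjusted p = 0.162 with an estimated correlation, range 0.00343, by fry, to 0.162). A glutamate synthase gene (Solyc03g083440.3) rose from 177 ± 35.6 to 566 ± 82.9 CPM. The call was lost without control replicate 1 (0.105) or 2 (0.0706), PSTVd-M replicate 1 (0.0692), 2 (0.0587) or 3 (0.0647), or PSTVd-S23 replicate 1 (0.0835), and with no normalization or other filters (0.0621 to 0.0801). Starch and sugar metabolism had 10 of 105 higher and 5 lower (10 and 6 over the list alone) and was not called (0.638). Its median of -0.07 became 0.20 with no normalization, and its mean was 0.04. Cell wall invertase Lin6 (Solyc10g083290.4), which splits sucrose, rose from 6.35 ± 2.04 to 95.2 ± 50.8 CPM. Phenylpropanoid and lignin synthesis had 7 of 52 higher and 2 lower (7 and 2 over the list alone, 0.774, median 0.07). Flavonoid synthesis had 2 of 19 lower (2 over the list alone, 0.0804), and its median of -0.24 became 0.03 with no normalization. The clock list had 7 of 42 higher and 8 lower (7 and 12 over the list alone, 0.4), with a median of -0.11 that became 0.18 with no normalization. A TOC1-like gene (Solyc03g115770.3) rose from 9.65 ± 5.16 to 74.8 ± 10.9 CPM, and a CONSTANS-like gene (Solyc03g119540.3) fell from 210.4 ± 40.8 to 73.8 ± 4.79 CPM.

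Among markers of cell types and states, genes of dividing cells had 1 of 199 higher and 34 lower (2 and 39 over the list alone), with a median of -0.41 (adjusted p = 3.14e-08, and adjusted p = 0.2 with an estimated correlation, range 4.94e-09 to 0.2). Cyclin cycd3c2 (Solyc01g107730.3) went from 27.3 ± 16.2 to 4.05 ± 3.75 CPM and histone H4 (Solyc06g075960.1) from 45.7 ± 6.23 to 20.3 ± 7.24 CPM. A kinesin light chain-related gene (Solyc03g114320.3), whose name ties it to transport rather than division, fell too. Xylem and secondary wall genes had 1 of 43 higher and 6 lower (1 and 6 over the list alone), with a median of -0.43 (adjusted p = 0.00184, and adjusted p = 0.324 with an estimated correlation, range 0.000205 to 0.324). They were not called by fry (0.0608). Phloem genes had 2 of 12 lower (2 over the list alone), with a median of -0.37 (adjusted p = 0.00751, and adjusted p = 0.162 with an estimated correlation, range 0.00107 to 0.162), both of the sieve element occlusion family. Epidermis and cuticle had 5 of 82 higher and 10 lower (5 and 11 over the list alone), with a median of -0.30 (adjusted p = 0.0169, and adjusted p = 0.394 with an estimated correlation, range 0.00405 to 0.394). They were lost without control replicate 3 (0.0554) or PSTVd-S23 replicate 2 (0.0802), and not called by fry (0.136). Trichome genes (1 of 13 higher, 2 lower, 1 and 3 over the list alone, median -0.72, adjusted p = 0.0927) and senescence genes (7 of 50 higher, 6 lower, the same over the list alone, median 0.01, 0.939) were not called.

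**Figure D3:**
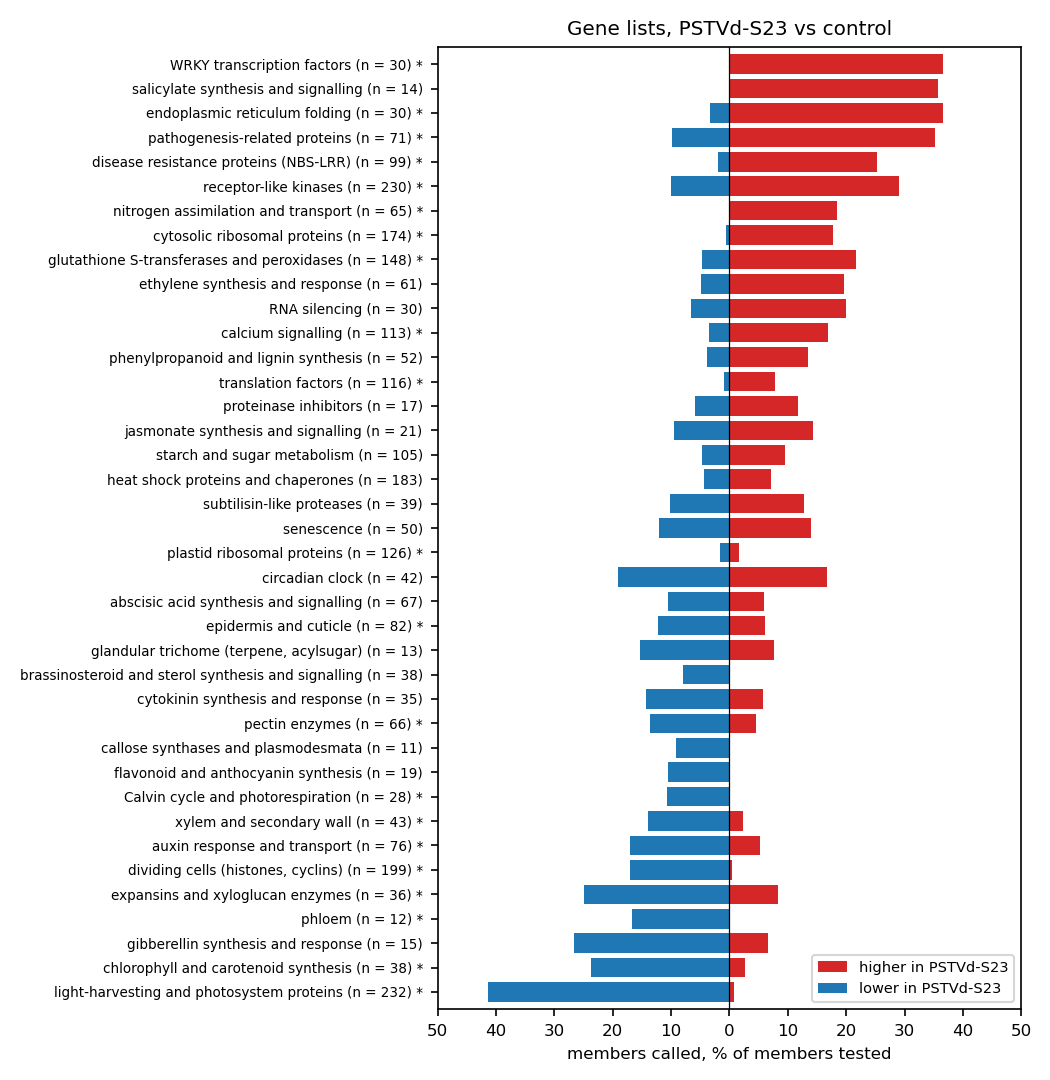
Share of the tested members of each of the 39 lists called higher (red) or lower (blue) in PSTVd-S23 against control, in % of members tested (n in brackets); an asterisk marks an adjusted p under 0.05 in the list test with the preset correlation. Of 232 light-harvesting and photosystem genes 96 were lower; medians of 12 lists change sign with no normalization, among called lists those of chlorophyll synthesis and plastid ribosomal proteins.

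Of the 39 lists 21 were called in PSTVd-S23, 10 toward higher and 11 toward lower values, and none with an estimated correlation. Fry called 19 lists, 16 of them among these, and also the brassinosteroid, callose and trichome lists. Placing genes without counts in a group at their bound moved no list median by more than 0.0256.

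The direct comparison of the severe with the mild strain asks which of these changes differ between strains. PR1 (Solyc00g174340.2) stood at 401 ± 226 CPM in PSTVd-S23 and 37.1 ± 23 in PSTVd-M, with 11.1 ± 4.51 in control (SD, n = 3), a log2 difference of 3.44 ± 0.45 (SE, adjusted p = 0.000349). Phosphoenolpyruvate carboxylase kinase was higher in PSTVd-S23, at 104 ± 16.0 against 22.9 ± 5.06 CPM (log2 2.18 ± 0.20, adjusted p = 7.31e-05). It was not called in PSTVd-S23 against control (log2 0.51 ± 0.18, adjusted p = 0.0779). Dicer-like 2b was higher, at 120.0 ± 26.3 against 41.1 ± 1.96 CPM (log2 1.53 ± 0.20, adjusted p = 0.000409). Cab5a was lower, at 41.7 ± 27.3 against 447 ± 70.7 CPM (log2 -3.40 ± 0.36, adjusted p = 0.000138), and Argonaute 10a too, at 18.5 ± 3.59 against 55.3 ± 9.54 CPM (log2 -1.60 ± 0.21, adjusted p = 0.000394).

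With edgeR 1083 genes differed, 623 higher and 460 lower in PSTVd-S23, of which 454 and 283 changed by at least 1 on the log2 scale. At an unadjusted p under 0.05 stood 3251 genes. The groups did not overlap for 26.6% of genes, against 10% by chance, and for 1069 of those called. The number called dropped to 463 and 449 without PSTVd-M replicates 1 and 2 and to 554 and 497 without PSTVd-S23 replicates 1 and 2. With no normalization the median of all genes shifted by 0.32 and the split became 1810 higher and 197 lower. Of the 1083 genes 920 were also called in PSTVd-S23 against control, 555 of them higher and 365 lower in both.

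Between strains 16 lists were called. Fry called 10, of which 9 were among these and the other was the list of glutathione S-transferases and peroxidases. With an estimated correlation 1 list was called, endoplasmic reticulum folding, with 9 of 30 members higher and none lower (11 and 1 over the list alone) and a median of 0.57 (adjusted p = 5.05e-07, and adjusted p = 0.0305 with an estimated correlation, range 2.28e-10 to 0.0305). Protein disulfide-isomerase stood at 319.5 ± 59.5 against 107 ± 7.29 CPM. Cytosolic ribosomal proteins had 18 of 174 higher (39 over the list alone), with a median of 0.39 (adjusted p = 3.28e-13, and adjusted p = 0.0686 with an estimated correlation, range 6.77e-16 to 0.0686). Light-harvesting and photosystem genes had 92 of 232 lower and none higher (135 and 3 over the list alone), with a median of -0.79 (adjusted p = 1.61e-39, and adjusted p = 0.149 with an estimated correlation, range 4.14e-46 to 0.149). Of these 232 members 76 are nuclear and the others are organelle copies. WRKY genes had 5 of 30 higher (9 over the list alone), with a median of 0.67 (adjusted p = 6.15e-05, and adjusted p = 0.287 with an estimated correlation, range 6.34e-07 to 0.287). They were not called by fry (0.0719), and the difference of WRKY81, 1.36 ± 0.35, was 2.11 without PSTVd-M replicate 3. WRKY16 (Solyc02g032950.3) stood at 40.9 ± 23.2 against 3.96 ± 1.86 CPM.

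Pathogenesis-related genes had 18 of 71 higher and 4 lower (24 and 5 over the list alone), with a median of 0.45 (adjusted p = 0.00995, and adjusted p = 0.287 with an estimated correlation, range 0.000292 to 0.287). The median was still positive with no normalization but the call was lost (0.146). NBS-LRR genes had 5 of 99 higher (3 over the list alone), receptor-like kinases 44 of 230 higher and 11 lower (59 and 20 over the list alone) and calcium genes 12 of 113 higher and 1 lower (14 and 1 over the list alone). Their medians were 0.27, 0.14 and 0.18, with adjusted p of 0.0180, 0.0236 and 0.0180, and adjusted p = 0.287 with an estimated correlation for each, the highest of ranges from 0.00413, 0.000311 and 0.00558. Resistance genes and receptor-like kinases were lost with no normalization (0.0513 and 0.0921), receptor-like kinases without PSTVd-M replicate 2 (0.0608), and calcium genes without PSTVd-M replicate 1 (0.0573). Fry did not call the calcium list (0.0571). Translation factors had 8 of 116 higher (8 over the list alone), with a median of 0.23 (adjusted p = 0.00520, and adjusted p = 0.287 with an estimated correlation, range 0.000189 to 0.287). Nitrogen genes had 9 of 65 higher (14 and 2 lower over the list alone), with a median of 0.34 (adjusted p = 0.0219, and adjusted p = 0.149 with an estimated correlation, range 0.00816, by fry, to 0.149). They were lost without PSTVd-M replicate 3 (0.111), with no normalization (0.0707) and under other filters (0.0610 and 0.0502).

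Toward lower values in PSTVd-S23 than in PSTVd-M, Calvin cycle genes had 3 of 28 members called (5 over the list alone), with a median of -0.50 (adjusted p = 6.85e-06, and adjusted p = 0.287 with an estimated correlation, range 4.64e-09 to 0.287), and were not called by fry (0.0719). Chlorophyll and carotenoid synthesis had 9 of 38 lower (10, and 2 higher, over the list alone), with a median of -0.30 that became 0.03 with no normalization (adjusted p = 6.85e-06, and adjusted p = 0.287 with an estimated correlation, range 1.33e-07 to 0.287). Pectin enzymes had 6 of 66 lower and 1 higher (the same over the list alone), with a median of -0.34 (adjusted p = 0.000914, and adjusted p = 0.314 with an estimated correlation, range 4.04e-05 to 0.314), and were not called by fry (0.0842). Dividing cells had 3 of 199 lower (0 over the list alone), with a median of -0.25 that became 0.07 with no normalization (adjusted p = 0.000329, and adjusted p = 0.321 with an estimated correlation, range 2.47e-06 to 0.321), and were not called by fry (0.106). Plastid ribosomal proteins had no member called (median -0.22, 0.11 with no normalization, adjusted p = 0.0285, and adjusted p = 0.388 with an estimated correlation, range 0.00625 to 0.475). They were lost without PSTVd-M replicate 1 (0.0667) or 2 (0.0815), without PSTVd-S23 replicate 2 (0.127), and at 0.0707 to 0.475 with no normalization, no filter or organelle copies left out, and fry did not call them (0.184). Xylem genes had 1 of 43 lower and 1 higher (0 and 1 over the list alone), with a median of -0.26 that became 0.06 with no normalization (adjusted p = 0.0180, and adjusted p = 0.388 with an estimated correlation, range 0.00192 to 0.388). They were lost without PSTVd-M replicate 1 (0.0777) or PSTVd-S23 replicate 2 (0.111), and not called by fry (0.173). The other 23 lists were not called, with adjusted p of 0.0639 to 0.827.

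An uneven gene between the strains was Solyc10g008840.3, of the Rab GTPase family of membrane traffic regulators. It had 13.4, 16.4 and 312.4 CPM in the PSTVd-M libraries, no counts in control and 3 in PSTVd-S23, and a PSTVd-M level 322-fold that in PSTVd-S23 with a counting interval of 110 to 1566. Its fitted log2 difference of -8.31 was -5.45 without PSTVd-M replicate 3, and PSTVd-M against control was not called (adjusted p = 0.0986, at least 346-fold higher). A glycosyltransferase gene (Solyc01g107780.3) stood at 64.9 ± 44.4 CPM in PSTVd-S23 with 3 counts in control, a ratio of 169 with a counting interval of 57.4 to 820.4.

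**Figure D4:**
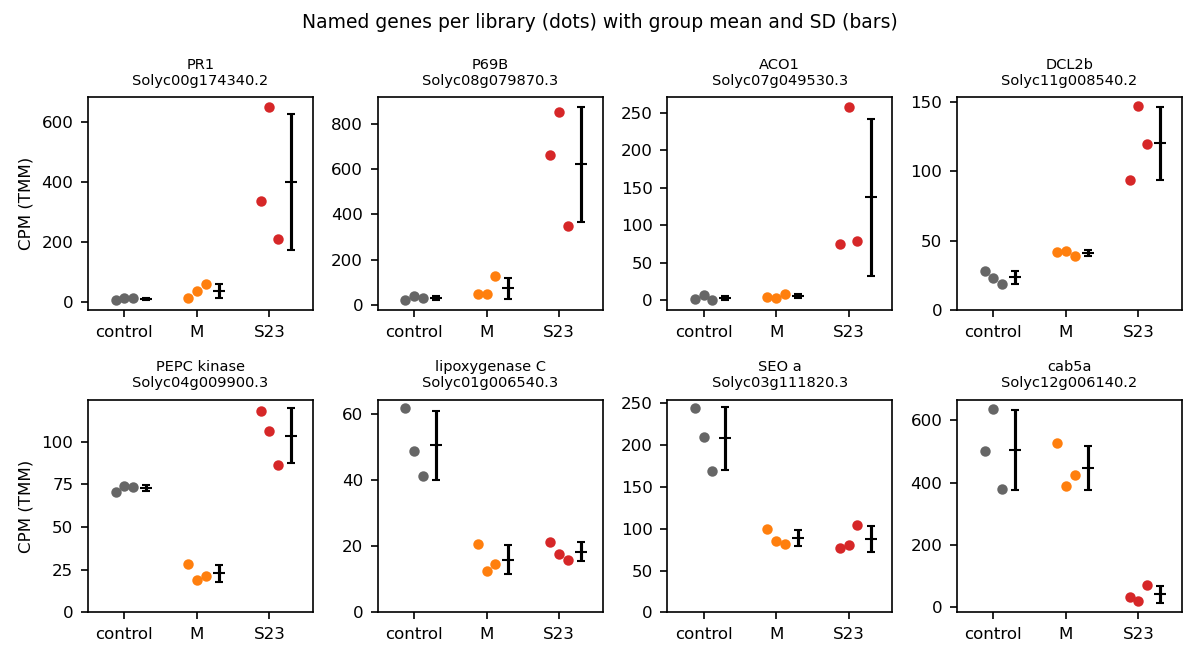
Levels of 8 named genes in CPM per library (dots) for control, PSTVd-M (M) and PSTVd-S23 (S23), with mean and SD of each group (bars, n = 3). PR1 stood at 11.1, 37.1 and 401 CPM and cab5a at 505, 447 and 41.7 CPM in the group means.

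The changes of the strains against control were set against each other to ask whether they share genes. Called in both and in the same direction were 3 genes, lipoxygenase C, Sn-1 and the sieve element occlusion gene, all lower. Their levels did not differ between strains by the test (log2 0.21 ± 0.26, 0.20 ± 0.24 and -0.02 ± 0.19, adjusted p = 0.704, 0.694 and 0.966). Independent sets of this size would share 0.246 genes toward lower values. Simulated data in which neither strain differed from control shared 0 to 1. That range is no reference for the observed overlap, since PSTVd-S23 was unchanged there too. The overlap with PSTVd-S23 changed was not simulated. With the filter, all 9 libraries and no replicate block edgeR called none higher in both. With no filter it called 191 genes in both, more than its 92 genes lower in PSTVd-M, so some were higher. DESeq2 called 35 genes in both and limma-voom 3. Without control replicate 1, control replicate 2, PSTVd-M replicate 2 or PSTVd-S23 replicate 1 the overlap was 0, and without PSTVd-S23 replicate 3 it was 5.

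Genes called with PSTVd-S23 leaned the same way in PSTVd-M, where only those 3 genes also passed the test. Those higher in PSTVd-S23 had a median log2 fold change of 0.45 in PSTVd-M, and 87.9% were positive. Without PSTVd-M replicate 3 that median was 0.29. Simulated data with PSTVd-M equal to control and PSTVd-S23 at its own mean gave 0.10 and 61.3%, since both comparisons use the same controls. Those lower in PSTVd-S23 had a median of -0.29 and 86.2% were negative, against -0.10 and 63.8% simulated. The covariance of the log2 fold changes across genes was 0.191. Simulated data with neither strain changed gave 0.0691 (0.0653 to 0.0731), a difference of 0.122. The correlation was 0.542, against 0.502 (0.484 to 0.527) in the same simulated data. It was not simulated with PSTVd-S23 changed, so the gap between 0.542 and 0.502 does not measure the excess over shared controls. Genes are not independent replicates.

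In the authors' table, 101 genes had a step-up adjusted p under 0.05 for the mild strain, 59 higher and 42 lower, and 2358 for the severe strain, 1279 higher and 1079 lower. Of the 101 genes 54 were tested here, 1 was called in both, and 51 had an unadjusted p under 0.05 here. Of the 2358 genes 1948 were tested here and 1430 were called in both in the same direction. Across 7080 well-counted genes the log2 ratios of the authors and those fitted here had a Pearson r of 0.976 for the mild and 0.994 for the severe strain, across genes that are not independent.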

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

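Among the tests in this part, those of near-identical chlorophyll a/b-binding gene copies and of a lower share of RNA from chloroplast-bearing cells were chosen only after the result was seen. The test of genes near absent from the other PSTVd-M libraries was added after the first mixing result but before its own.

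A difference between the groups of the strains marked 3 results for a closer look. In PSTVd-S23 623 genes were higher and 460 lower than in PSTVd-M. The phosphoenolpyruvate carboxylase kinase gene Solyc04g009900.3 differed by 2.18 on the log2 scale, with PSTVd-M below control and PSTVd-S23 not called against it.

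PSTVd-M replicate 3 lay nearer to PSTVd-S23 than the other libraries of its group. RNA or reads of PSTVd-S23 leaves mixed into it would give the same share from genes higher and from genes lower in PSTVd-S23. Against the PSTVd-S23 mean the shares were 19.4% (16.6 to 22.5) and 22.7% (14.3 to 27.4), a difference of -3.32 points. Brackets are 95% bootstrap intervals over genes and hold no error between libraries. Against PSTVd-S23 replicates 1, 2 and 3 the shares were 21.1 and 20.4%, 12.8 and 18.2%, and 27.6 and 28.4%. The differences were 0.66, -5.48 and -0.81 points, and the intervals of each pair overlapped. In 26 genes near absent from the other PSTVd-M libraries, the SD of the log2 ratio to PSTVd-S23 was 1.32, against highest simulated values of 0.732, 0.684 and 1.40 for a mixture with PSTVd-S23 replicates 1, 2 and 3, so 0.940 of the highest. Mixing with replicate 3 stays open. The residual correlation of these 2 libraries, -0.261, cannot decide it, since deviations were taken from group means. PSTVd-M replicate 3 had the highest score of its group (39.9%) and PSTVd-S23 replicate 3 the lowest of its own (82.3%). The spread exceeds 1.5 times that of mixtures with replicate 1 or 2. Those mixtures were simulated with counting error only and no variation between plants, so replicates 1 and 2 are not excluded. Depth does not account for the gap in score of PSTVd-M replicate 3, which was 0.957 of its size after thinning. An earlier or stronger response of the plant material of PSTVd-M replicate 3 was not tested.

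Nuclear light-harvesting and photosystem genes were lower in PSTVd-S23 than in control. The 3 scalings tried do not account for it, since the median nearest to 0 among them was -0.90. All of them are relative to the library counts, so a change in total RNA per leaf could not be tested. Movement of reads between near-identical copies would leave their sum unchanged, but the summed chlorophyll a/b-binding level differed by -2.06 on the log2 scale. A lower share of chloroplast-bearing cells would lower nuclear plastid ribosomal protein genes as much only if both sets lie in the same cells. The medians differed by 1.07, against a sum of bootstrap SE of 0.187. These SE are over genes and not over plants. The sets thus did not fall alike, but how they are spread over leaf cells was not measured. A change in cell composition therefore stays open. A lower expression of the light-harvesting and photosystem genes and a change in cell composition are hypotheses left by these tests, with other causes untested.

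The authors' table holds more genes for the mild strain than the 4 called here. The filter used here does not account for the 47 authors' genes not tested here, of which edgeR with no filter called 0. An effect of low counts in the authors' own test was not tested and stays open, since 49 of the 101 genes had a mean count under 10 and 44 had a group without counts. For the 54 tested here, the residual spread of each gene was at the median 0.335 of the spread shared from other genes, against 0.950 over all genes. A test that uses each gene's own small spread stays open, since edgeR with no filter, where the spread is fully shared, called 17 of these 54 genes and the authors' test is not given in the sources used here.

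Other splits of the 6 libraries in each comparison number 10 with the real one, too few for a share under 0.05. For genes, the real split gave 4 in PSTVd-M against control, 2116 in PSTVd-S23 against control and 1083 between strains, and the highest other split 0, 0 and 25, so that 1 split reached the real number in each. For lists, the real split gave 4, 21 and 16 and the highest other 4, 12 and 13, and 2, 1 and 1 splits reached the real number.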

How the results depend on the processing

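Only the tests by fry, with organelle copies left out of the lists and of the shift without PSTVd-M replicate 3 were chosen after the data were seen. No list, and no named gene followed, was called in the opposite direction under any setting. Genes named only as list members of the other comparisons were not followed. With no normalization the medians of 12 lists changed sign in PSTVd-S23 against control. In PSTVd-S23 against control the number of genes was 2066 to 2799 over other tools, scalings and filters, 1820 with only the 6 samples compared, and 1309 to 2486 with 1 library left out, the lowest without PSTVd-S23 replicate 2 and the highest without replicate 3. In PSTVd-M against control limma-voom, DESeq2 size factors, no normalization and the stricter filter each kept the 4 genes. DESeq2 called 48 and edgeR with no filter 239 (147 higher, 92 lower), where the prior degrees of freedom were infinite against 9.65, and the cause was not tested. With only the 6 samples compared it was 7, from fewer samples. With 1 library left out it was 0 (PSTVd-M replicate 2) to 6 (PSTVd-M replicate 1). Between strains no normalization gave 2007 and no filter 1747, and left-out libraries gave 449 (PSTVd-M replicate 2) to 1519 (PSTVd-S23 replicate 3), causes not tested. The overlap was 35 by DESeq2, 191 with no filter and 5 with only the 6 samples, and 0 (without control replicate 1) to 5 (without PSTVd-S23 replicate 3). Lists in PSTVd-M numbered 1 with no filter, 0 with an estimated correlation, 0 by fry, 0 without control replicate 3 and 7 without PSTVd-M replicate 1. An estimated correlation gave 0 lists in PSTVd-S23 against control and 1 between strains. Fry gave 10 between strains, 9 of them among the 16, causes not tested.

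A replicate block gave 5, 1854 and 855 genes, an overlap of 2 and 5, 21 and 16 lists. Replicate numbers showed no clear pairing of the libraries, as 2 of 9 correlations of equal numbers passed 0.1. The labels do not say whether a number marks a shared tray or day, and these correlations cannot exclude it. Scaling to the added RNA standards was not run, since the table used here holds 0 of them. The lowest total, 1560631 counts, limits calls of genes with few reads.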

Other observations

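The families and viroid-named genes in this part were chosen only after the data were seen, and the simulated range without PSTVd-M replicate 3 was computed after its value was seen.

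Transcription factor families not among the 39 lists differed in direction in PSTVd-S23 against control. Of 15 gene families looked at, 9 had an adjusted p under 0.05 in the list test and none with an estimated correlation. NAC genes, many of them stress and senescence regulators, had 5 of 20 members higher and 1 lower (6 and 2 over the family alone), with a median of 0.46 (adjusted p = 0.00584, and adjusted p = 0.114 with an estimated correlation). Solyc06g060230.3 (SL3.0 chromosome 6, 38303221 to 38305530) rose from 15.6 ± 4.30 to 75.3 ± 19.2 CPM (SD, n = 3). Growth-regulating factors and their GIF partners, which promote leaf growth, had 2 of 7 lower (4 over the family alone), with a median of -1.32 (adjusted p = 0.00584, and adjusted p = 0.158 with an estimated correlation). Of the 15 families it alone had an adjusted p under 0.05 in PSTVd-M against control too (0.0113), at the preset correlation, and an estimated correlation was not tried there. The GIF gene Solyc11g006230.2 stood at 9.09 ± 2.52 CPM in control and had 3 counts in PSTVd-S23, 28.2-fold lower with a counting interval of 9.32 to 140. Genes of bHLH factors had 8 of 73 lower and 1 higher, with a median of -0.38 (adjusted p = 0.00584, and adjusted p = 0.0508 with an estimated correlation). That median was -0.09 with no normalization. Proteasome genes had 4 of 38 higher (1 over the family alone), with a median of 0.37 (adjusted p = 0.000965, and adjusted p = 0.109 with an estimated correlation).

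An ABC transporter gene (Solyc06g009290.3, chromosome 6, 3247971 to 3256359) rose from 22.3 ± 2.29 to 244 ± 88.3 CPM (log2 3.46 ± 0.27, adjusted p = 6.1e-06). The gene of NAD(P)H-ubiquinone oxidoreductase B2 (Solyc02g079170.3, chromosome 2, 44337085 to 44343055), of the mitochondrial electron chain, rose from 5.35 ± 3.72 to 88.0 ± 30.2 CPM (log2 4.13 ± 0.39, adjusted p = 1.72e-05). Of 6 genes whose symbol or description refers to a viroid, 3 were tested. The gene cevi1 (Solyc01g006300.3) rose from 22.3 ± 8.96 to 267 ± 133 CPM (adjusted p = 3.89e-05) and the lipid desaturase cevi19 (Solyc12g044950.2) had a log2 fold change of 3.85 ± 0.36 (adjusted p = 1.39e-05). GABA-TP2 (Solyc12g006470.2), described as a binding protein of viroid RNA, was not called (log2 -0.20, adjusted p = 0.733).

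Most genes changed by PSTVd-S23 were shifted the same way in PSTVd-M. The hypothesis was a weaker form of the PSTVd-S23 change in PSTVd-M. Without PSTVd-M replicate 3 the genes higher in PSTVd-S23 had a median of 0.29 in PSTVd-M. In 10 simulated data sets without that library, in which PSTVd-M equals control, it was 0.0801 to 0.127. Those lower had -0.26, against -0.13 to -0.10. These medians go with a weaker form, but not all genes or lists follow it. The simulated data share their controls too, but draw each gene independently, so part of the excess may come from the shared controls where these deviate in many genes at once. The controls are too few to be divided between the comparisons with 2 libraries each. Of the 1083 genes that differed between strains, 415 (38.3%) had opposite signs against control in PSTVd-M and PSTVd-S23. Of these, 257 were called in PSTVd-S23 against control and 1 in PSTVd-M. Choosing genes by a difference between strains favours opposite signs. Resistance genes lay above the control mean in all PSTVd-M and PSTVd-S23 libraries. Light-harvesting genes lay above it in PSTVd-M replicates 1 and 2 and below it in all PSTVd-S23 libraries.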
